A study of Mus musculus with 9 samples.

How the data were processed

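RNA was measured in 9 libraries of endothelial cells sorted from the lungs of adult mice, 3 libraries for each of 3 genotypes. Per the labels' protocols, cells without DAPI and CD45 signal and with CD31 signal were sorted from C57BL/6 mice 6 weeks old. RNA was extracted with a DNase step, ribosomal RNA was depleted and strand-specific total RNA libraries were made in a single batch, per the labels' protocols. Whether the 3 libraries of a genotype came from separate mice is not given in the sources used here, so p-values measure only the spread between these libraries.

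The values are whole-number read counts per gene, not normalized, deposited by the authors as a single table. Counting used featureCounts version 2.0.1 with the Ensembl annotation release 107 of genome build GRCm39, per the file headers. The submitters' processing notes name STAR 2.7 and featureCounts, and they name the genome build as mm10, which differs from the header. Coordinates here are those of the deposited table, on GRCm39. The recorded command has no option for strand, for read pairs or for reads that map to several places, per the file headers. Values of genes that overlap another gene or have a near-identical copy are therefore uncertain. Between 76.6% and 89% of the counts below 200 in a library were even numbers, so many fragments appear to enter as a pair of counts. Use of the kit's molecular identifiers is not given in the sources used here. The floors given for 0 counts therefore cover counting error only, while SEs and p-values come from the spread between libraries.

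The table holds 56748 gene identifiers. Symbols came from a mouse annotation on the earlier build GRCm38, used for names and gene types only, in which 52073 of the identifiers were found. Genes without a symbol took between 0.891% and 1.3% of the counts of a library. Total counts ran from 15522100 to 27842496 per library, and between 21002 and 25562 genes had at least a single count.

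Genes were kept by the default rule of filterByExpr with genotype as the group, which left 19486 genes. Differences were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, and a quasi-likelihood model with robust estimation was fitted to all 9 libraries with genotype as the only term. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are given on the log2 scale with standard errors (SE). Each SE is the absolute log2 fold change divided by the square root of the test's F statistic. It therefore restates the test and is no separate measure of spread. Levels are given as CPM, the deposited count of a gene relative to the scaled library size. Where every library of a group had 0 counts, the fold was computed against a floor of 3 counts per library and is a lower bound.

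A set of 39 gene lists (pathways, endothelial subtypes, and markers of other lung and blood cells) held 967 genes, of which 896 were tested. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, again with a correlation estimated for each list, and with fry. The genes named in the text follow a rule with several parts: the Notch receptors, Rbpj, Maml1 and the Notch targets past the threshold; the 8 largest changes each way against WT, and the first 5 each way between Notch1f/f and DNMAML. These largest changes were limited to genes past the threshold with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a clone or model name. The rule adds up to 4 members of each list with a gene past the threshold and 2 of each other list, and up to 6 genes each way past the threshold in both comparisons with WT. The design, the lists, this rule and most of the other settings tried were fixed before the data were examined.

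The test was run on simulated data, with counts drawn for the real genes and known changes. It recovered 20.8% of 2-fold and 51.6% of 4-fold changes for DNMAML against WT, with 1 false call among 70. For Notch1f/f against WT it recovered 16.3% and 51%, with 4 false calls among 68. For Notch1f/f against DNMAML it recovered 20.2% and 48.4%, with 5 false calls among 70. At this depth and number of libraries, most 2-fold changes would not pass. The simulated genes were drawn independently of each other, while real genes deviated together between libraries. The shares recovered and the false calls therefore need not hold for the real data.

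The labels number the libraries of each genotype from 1 to 3 and do not say what a number marks. Whether it pairs libraries was therefore read from the data, as the correlation of their deviations from the group means. Same-numbered WT and DNMAML libraries gave 0.238, 0.344 and 0.179, and differently numbered ones -0.27 to 0.0774, so the number was taken to pair these 6 libraries. Same-numbered libraries gave -0.13 to 0.191 for WT with Notch1f/f and -0.12 to 0.212 for DNMAML with Notch1f/f. The number was therefore not taken to pair the Notch1f/f libraries. Differently numbered libraries of these 2 comparisons gave up to 0.352 and 0.306. Correlations of this size thus do not show a pairing, and the pairing of WT with DNMAML is an assumption read from the same data.

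Alternatives were other size factors, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust estimation, only the 6 libraries compared, the replicate number as a block, counts without mitochondrial, ribosomal RNA and haemoglobin genes, stricter thresholds and each library left out in turn. Terms for sex, for leukocyte markers and for the library of each genotype with the lowest Fos, the block in the 6 paired libraries alone, halved counts and the legacy quasi-likelihood fit were added later. Lists of p53 targets and of circadian genes were also added later. No column of the table was left out.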

Results

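Notch signalling in lung endothelium was examined in 9 RNA libraries from sorted mouse lung endothelial cells. WT mice, DNMAML mice and Notch1f/f mice gave 3 libraries each. DNMAML is the usual name of a dominant-negative Mastermind-like protein, which blocks transcription by the Notch receptors, and Notch1f/f is the usual notation for a conditional allele of Notch1. The recombinase and its driver are not given in the sources used here. Total counts were 19832247, 15522100 and 20080217 in WT, 25025551, 19846041 and 27842496 in DNMAML, and 21430631, 21820680 and 18226695 in Notch1f/f libraries. The endothelial genes Cdh5 and Pecam1 were high in each library, with Cdh5 between 5370 and 6660 CPM. Replicate 2 of WT, replicates 1 and 3 of DNMAML and replicate 1 of Notch1f/f expressed Y-linked genes, so both sexes were present.

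Notch1 (ENSMUSG00000026923, chromosome 2, 26347915 to 26406675, GRCm39), the receptor named by the Notch1f/f label, was measured at 766, 909 and 811 CPM in WT libraries. DNMAML libraries had 679, 872 and 777 CPM of Notch1. Notch1f/f libraries had 70.8, 29.5 and 176 CPM of Notch1, each below every library of the other genotypes. The log2 difference of Notch1 between Notch1f/f and WT was -3.17 (SE 0.59, n = 3 per group), a 9-fold lower mean. This missed the threshold in the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0634). The difference passed with DESeq2 at an adjusted p = 3.17e-06. Over all settings the adjusted p ran from 2.33e-66, in the edgeR test without a filter, to 0.198. The fit without a filter had the same log2 difference, so its p is not taken as a measure of the spread between libraries. In the edgeR test Notch1 passed without Notch1f/f replicate 2 (log2 change -2.74, Benjamini-Hochberg adjusted p = 0.0381) and without Notch1f/f replicate 3 (-4.05, adjusted p = 0.0093). Maml1, whose product is the family member after which the DNMAML construct is named, had 75.0 ± 14.5 CPM in WT and 78.5 ± 3.03 in DNMAML (SD, n = 3). The log2 difference of Maml1 was 0.07 (SE 0.15), within the spread of the libraries. Gene totals need not show a deleted exon or a transgene, so these values check the labels only in part. Rbpj, the DNA-binding partner of Notch, and Notch4 also differed from WT by less than 0.12 on the log2 scale in both genotypes.

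**Figure D1:**
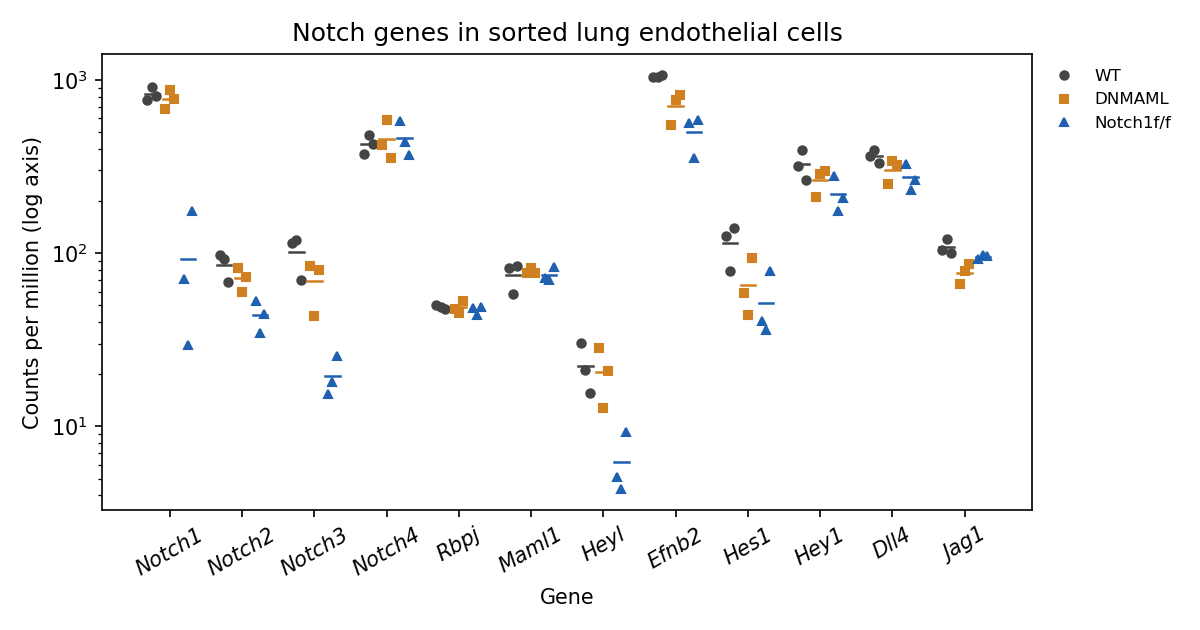
CPM values on a log axis of Notch receptors, Rbpj, Maml1 and Notch targets; each symbol is a library, 3 per genotype, and each bar is a group mean. Notch1 lies between 29.5 and 176 in Notch1f/f libraries and between 679 and 909 in the others.

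The comparison of DNMAML with WT asks which genes differ with a genotype named after a construct that blocks transcription by Notch receptors. Whether that transcription was blocked in these cells was not tested. Aspm (chromosome 1, 139382510 to 139421829, GRCm39), a protein of the mitotic spindle, was the only gene past the threshold among 19486 tested. Aspm rose from 1.60 ± 0.29 CPM in WT to 19.3 ± 2.22 CPM in DNMAML (SD, n = 3), a log2 change of 3.59 (SE 0.40). The edgeR quasi-likelihood test gave Aspm a Benjamini-Hochberg adjusted p = 0.0244. Values of other cell cycle genes did not pass: the proliferation marker Mki67 had 5.51, 7.18 and 5.96 CPM in WT and 122, 146 and 103 CPM in DNMAML libraries. The cyclin Ccnd1 had 170 ± 18.6 CPM in WT and 408 ± 62.6 CPM in DNMAML. All 51 tested members of the cell cycle list were higher in DNMAML, with a median log2 difference of 2.21. Adjusted over the list alone, 40 of them passed, and 0 passed over all genes. The list was higher by camera (Benjamini-Hochberg adjusted p = 3.64e-33), and had an adjusted p = 0.571 with an estimated correlation. Markers of leukocytes moved with these genes in part: Ptprc, which encodes CD45, had 4.99, 2.95 and 0.408 CPM in WT and 28, 26.7 and 1.39 CPM in DNMAML. The lists of leukocyte, macrophage and neutrophil markers had median log2 differences of 1.48, 1.30 and 2.99, with an adjusted p = 0.643 with an estimated correlation for each. Il1b, a cytokine on the neutrophil list, was the only member of these 3 lists that passed when adjusted over the list alone. The sort removed cells with CD45 signal, per the labels.

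None of the Notch targets or vessel genes passed over all genes in DNMAML in the fit to all 9 libraries without a block. The Notch target list had a median log2 difference of -0.24, with 19 of 26 tested members lower. Camera called it (adjusted p = 0.00459), with an adjusted p = 0.571 with an estimated correlation. Over all genes 0 of its members passed; adjusted over the list alone, Jag1, a Notch ligand, was lower with a log2 difference of -0.48 (SE 0.13), and Ccnd1, which is also on the cell cycle list, was higher. The targets Hes1 and Efnb2 had log2 differences of -0.81 (SE 0.38) and -0.56 (SE 0.20), which did not pass. Arterial, venous, general capillary, pan-endothelial, shear and alveolar epithelial lists were also lower by camera, with medians of -0.19, -0.12, -0.12, -0.09, -0.10 and -0.24. Their adjusted p with an estimated correlation was 0.571 or more. Lists for tip and sprouting genes (median 0.18), interferon response (0.34), matrix genes (0.31) and antigen presentation (0.20) were higher by camera, with an adjusted p = 0.643 with an estimated correlation for the first 3 and 0.884 for antigen presentation. Of the tip and sprouting list, Apln, Cd34, Col4a2 and Sparc were higher and Esm1 and Vegfc lower when adjusted over the list alone. The log2 difference of Esm1, a gene of tip cells, was -1.40 (SE 0.28), and that of Vegfc was -1.52 (SE 0.32).

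WT and DNMAML libraries with the same replicate number deviated together, so the comparison was also fitted to these 6 libraries with the number as a block. This left 2 residual degrees of freedom. The pairing is an assumption read from the same data, and the fit was added after the data had been seen. By their Y-linked genes, each pair held a male and a female library: replicate 2 was male in WT, and replicates 1 and 3 in DNMAML. The fit had no term for sex, so differences within a pair are also differences between sexes. In that fit 212 genes rose and 98 fell among 18117 tested, and with the block in all 9 libraries 2 rose and 2 fell, Aspm rising in both. The 6 libraries without the block gave 65 higher and 13 lower, among them Ccnd1 and Cd34, which rose by 1.26 (SE 0.14) and 0.98 (SE 0.16), and Vwf, which fell by 1.03 (SE 0.17). There 20 genes of the cell cycle list already rose over all genes. Mki67 was among them (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.61e-05). With the block, 72 genes of the fixed lists passed over all genes, 52 higher and 20 lower. Of the cell cycle list 33 genes rose over all genes, among them Mki67 by 4.31 (SE 0.12) and Ccnd1 by 1.26 (SE 0.11). Markers of leukocytes rose with them: Ptprc by 2.62 (SE 0.30), the macrophage genes Ccr2 and Tyrobp by 3.90 (SE 0.56) and 3.60 (SE 0.73), and Il1b by 3.50 (SE 0.41). Adjusted over the list alone, 6 leukocyte, 8 macrophage and 2 neutrophil genes were then higher and 1 macrophage gene lower. Of the Notch targets Hes1, Gja5 and Efnb2 fell, with log2 changes of -0.84 (SE 0.11), -0.79 (SE 0.13) and -0.58 (SE 0.12), and Ccnd1 rose. Of the tip and sprouting genes Apln, Aplnr and Cd34 rose by 0.87, 0.57 and 1.00, and Esm1 and Vegfc fell by 1.41 and 1.56. Of the arterial list 4 genes fell and of the venous list 3. The endothelial gene Vwf, which encodes von Willebrand factor, fell by 1.04 (SE 0.13). Benjamini-Hochberg adjusted p values of the genes named here ran from 1.05e-07 for Mki67 to 0.0489 for Aplnr in the edgeR quasi-likelihood test with the block. The 15 lists called by camera were called in this fit too. It added as lower the immediate early, BMP and glycolysis lists, with medians of -0.10, -0.17 and -0.06. It added as higher the mitochondrial, platelet and erythroid, fibroblast and neural lists, with medians of 0.14, 0.07, 0.09 and 0.32. With an estimated correlation no list passed in this fit (lowest adjusted p = 0.383; 0.437 with the block in all 9 libraries).

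For DNMAML against WT, edgeR called 1 gene higher and 0 lower; 1164 genes (5.97%) had an unadjusted p below 0.05, where chance gives 974. DESeq2 called 177 higher and 38 lower, and limma-voom called 0 of either. In 14.4% of genes the groups did not overlap, where chance gives 10%. The call of Aspm was lost without WT replicate 1, 2 or 3 or DNMAML replicate 1 or 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.276, 0.131, 0.143, 0.0844 and 0.0753; 6.5e-19 to 0.333 over all settings), while its log2 difference was 3.48 to 3.74 in these fits. The number of higher genes was 84 without Notch1f/f replicate 1, 7 without Notch1f/f replicate 3, 4 without DNMAML replicate 3 and 2 without Notch1f/f replicate 2, and that of lower genes was 10 without Notch1f/f replicate 1.

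**Figure D2:**
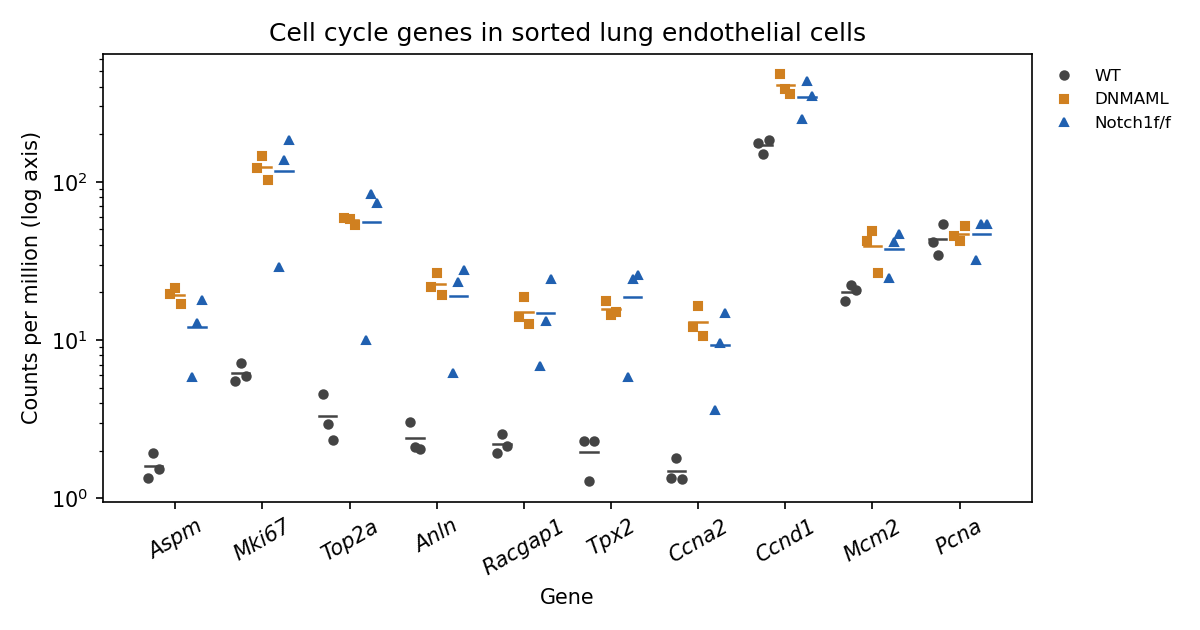
CPM values on a log axis of cell cycle genes; each symbol is a library, 3 per genotype, and each bar is a group mean. Mki67 lies between 5.51 and 7.18 in WT, between 103 and 146 in DNMAML and between 29.1 and 184 in Notch1f/f libraries.

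The comparison of Notch1f/f with WT asks which genes differ when the conditional allele of Notch1 is carried. In Notch1f/f libraries 100 genes rose and 63 fell. Among the Notch targets Notch3, Efnb2 and Heyl fell, with log2 changes of -2.36 (SE 0.32), -1.06 (SE 0.20) and -1.85 (SE 0.38), and Ccnd1 rose by 1.02 (SE 0.19, n = 3 per group). Notch2 fell too, from 85.8 ± 15.5 CPM to 44.1 ± 9.46 CPM, a log2 change of -0.96 (SE 0.19). Their Benjamini-Hochberg adjusted p values in the edgeR quasi-likelihood test ran from 0.0165 for Notch3 to 0.0482 for Heyl. Adjusted over the list alone, 12 Notch targets were lower and 3 higher, among them Hes1 at -1.15 (SE 0.39), Hey1 at -0.57 (SE 0.21) and Dll4 at -0.41 (SE 0.16). The list had a median of -0.40 (camera, adjusted p = 0.000122), with an adjusted p = 0.724 with an estimated correlation. Markers of mural cells moved with it: their list had a median of -1.27, and Notch3 is a member of both lists.

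Tip and sprouting genes were higher in Notch1f/f. Of 34 tip and sprouting genes 6 rose over all genes: Cd34, Aplnr, Col4a1, Col4a2, Sparc and Trp53i11. Cd34, a surface sialomucin, rose from 400 ± 77.2 CPM to 1098 ± 321 CPM (SD, n = 3), a log2 change of 1.46 (SE 0.21). The collagen IV genes Col4a1 and Col4a2, which lie head to head and overlap at their starts, rose by 1.67 each (SE 0.28 and 0.27). Adjusted over the list alone, 11 members were higher and 2 lower. The members Esm1 and Apln, named above for DNMAML, had log2 differences of 0.14 (SE 0.27) and 0.30 (SE 0.20), which did not pass. The list's median was 0.39 (camera, adjusted p = 1.92e-05), with an adjusted p = 0.724 with an estimated correlation. Matrix gene Col15a1 rose by 3.16 (SE 0.38), gap junction gene Gja1 by 2.10 (SE 0.32), cholesterol exporter Abca1 by 2.07 (SE 0.30) and growth factor gene Bmp2 by 2.79 (SE 0.53). Xaf1, an interferon-induced gene, rose by 1.06 (SE 0.13), while the interferon list as a whole had a median of 0.03. Of the aerocyte list, markers of the capillary cells specialised for gas exchange, Tmcc2 fell by 1.27 (SE 0.21), from 644 ± 26 CPM to 267 ± 78.5 CPM. The aerocyte list had a median of -0.48, with 23 of 28 members lower and 9 lower and 2 higher when adjusted over the list alone (camera, adjusted p = 4.13e-07). That list had an adjusted p = 0.724 with an estimated correlation. Hilpda, a lipid droplet protein, fell by 1.66 (SE 0.27), the chemokine Cx3cl1 by 1.40 (SE 0.22), Hgf by 0.86 (SE 0.16) and the noncoding RNA Rian by 2.28 (SE 0.46). The arterial, venous and pan-endothelial lists had medians of -0.06, 0.06 and -0.12 and were not called by camera.

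**Figure D3:**
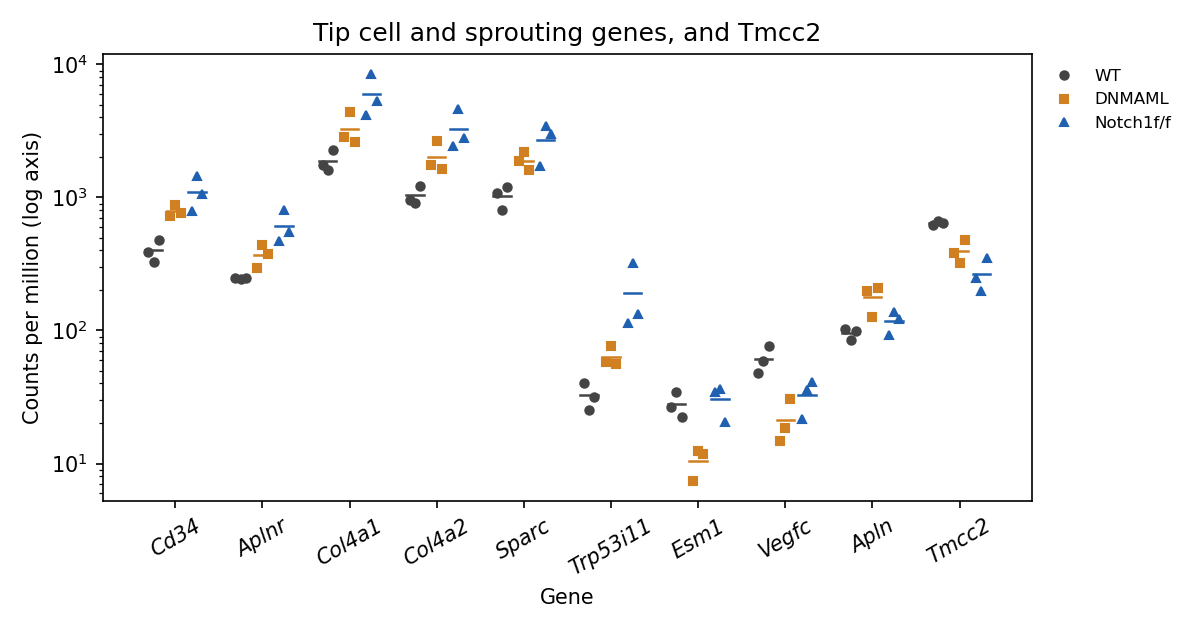
CPM values on a log axis of tip and sprouting genes and of the aerocyte gene Tmcc2; each symbol is a library, 3 per genotype, and each bar is a group mean. Col4a1 lies between 1620 and 2290 in WT and between 4180 and 8430 in Notch1f/f libraries.

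Cell cycle genes were higher in Notch1f/f as well. All 51 tested members were higher, with a median log2 difference of 2.60; 12 rose over all genes and 40 passed when adjusted over the list alone. Racgap1, Tpx2 and Anln, which act in cell division, rose by 2.74 (SE 0.42), 3.25 (SE 0.50) and 2.99 (SE 0.48). Mki67 had 29.1, 138 and 184 CPM in the 3 Notch1f/f libraries. Ptprc had 14.5, 4.96 and 1.58 CPM in the same libraries. The lists of leukocyte, macrophage and neutrophil markers had medians of 0.62, 0.98 and 1.08 and were not called by camera. The cell cycle list was called by camera (adjusted p = 3.62e-18), with an adjusted p = 0.724 with an estimated correlation. Several genes in this group were near the detection limit in WT: Cenpm and Shcbp1 had 0 counts in each WT library and were at least 15.1-fold and 14.3-fold higher, against a floor of 3 counts per library. Ccnb1, a mitotic cyclin, rose from 0, 2 and 2 counts in WT to 6.09 ± 5.00 CPM in Notch1f/f, and the calcium channel gene Cacna1h from 5, 1 and 2 counts to 6.49 ± 4.2 CPM. Other large rises were those of Ckap2 (log2 change 4.88, SE 0.87), Dtl (4.74, SE 0.92) and Snph (4.67, SE 0.92). The mitochondrial gene mt-Nd3 rose by 5.27 (SE 0.47), from 1.75 ± 0.74 CPM to 68.4 ± 13.0 CPM; it has a near-identical copy in the nucleus, Gm28438, so its value is uncertain. The 13 mitochondrial protein genes had a median of 0.45 (camera, adjusted p = 0.0238), with an adjusted p = 0.842 with an estimated correlation.

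Genes of mural cells, the pericytes and smooth muscle around vessels, were lower in Notch1f/f. Pdgfrb fell from 203 ± 47.2 CPM to 40.5 ± 12.1 CPM (SD, n = 3), a log2 change of -2.33 (SE 0.32), and Cspg4, Higd1b and Gucy1a1 fell by 2.14 (SE 0.32), 2.05 (SE 0.37) and 2.32 (SE 0.37). Of 23 tested mural genes 5 fell, among them Notch3, which is also on the Notch target list, and 0 rose. Adjusted over the list alone, 11 were lower and 1, Rgs5, was higher at 0.60 (SE 0.18). The smooth muscle genes Acta2 and Myh11 had log2 differences of -0.31 (SE 0.41) and -0.98 (SE 0.33). The mural list had a median of -1.27 (camera, adjusted p = 7.92e-08), with an adjusted p = 0.724 with an estimated correlation. Markers of other lung cells moved the same way: fibroblast genes had a median of -0.95 and alveolar epithelial genes, of which 28 of 28 were lower, a median of -0.86. Both were called by camera (adjusted p = 7.85e-06), with an adjusted p = 0.781 with an estimated correlation, and 0 genes of either passed over all genes. Further falls were those of Pcdh18 (log2 change -2.71, SE 0.39), Kcnq5 (-2.56, SE 0.48), Trpc1 (-2.47, SE 0.42), Pag1 (-2.44, SE 0.30) and Fam162b (-3.22, SE 0.58). Wfdc8 fell from 3.03 ± 1.25 CPM in WT to 0, 0 and 2 counts in the Notch1f/f libraries. Klk1b22, a kallikrein with near-identical relatives, and the small RNA gene Rprl3, which also has copies, had 0 counts in each Notch1f/f library, at least 26-fold and 57.9-fold lower than in WT; both are uncertain.

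**Figure D4:**
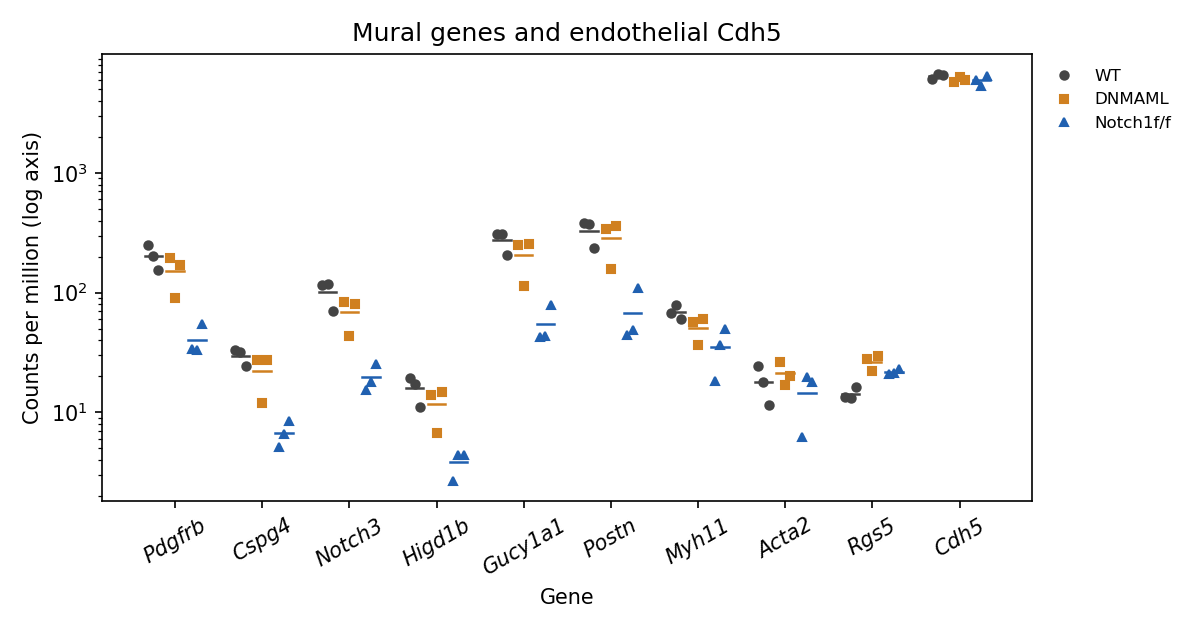
CPM values on a log axis of mural genes and of the endothelial gene Cdh5; each symbol is a library, 3 per genotype, and each bar is a group mean. Pdgfrb lies between 156 and 251 in WT and between 33 and 54.5 in Notch1f/f libraries.

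For Notch1f/f against WT, 2620 genes (13.4%) had an unadjusted p below 0.05, and the groups did not overlap in 17.8% of genes, where chance gives 10%. DESeq2 called 534 higher and 466 lower and limma-voom 36 and 33; of the 163 genes called by edgeR, DESeq2 called 163 and limma-voom 60. The higher count was 8, 11 and 23 without WT replicate 1, 2 or 3, 25 without Notch1f/f replicate 2, 162 without DNMAML replicate 2 and 369 without Notch1f/f replicate 1. The lower count was 5, 7 and 24 without WT replicate 1, 2 or 3, 11 without Notch1f/f replicate 2, 160 without DNMAML replicate 2, and 161 and 159 without Notch1f/f replicate 1 or 3.

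Notch1f/f and DNMAML were compared directly to test the difference between them. In Notch1f/f, mt-Nd3 rose by 4.50 (SE 0.45) and Cmtm8, a membrane protein gene, by 2.05 (SE 0.24), from 8.67 ± 1.5 CPM to 35.8 ± 6.22 CPM (SD, n = 3). Rprl3 fell to 0 counts in each Notch1f/f library, at least 71.6-fold lower, and Gm28438, chosen after its values were seen, fell by 2.64 (SE 0.24). Adjusted p values of these 4 genes ran from 0.00309 to 0.0101 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Notch1 had a log2 difference of -3.08 (SE 0.59) and Notch3 of -1.82 (SE 0.31), neither past the threshold; without Notch1f/f replicate 3 Notch1 passed in the edgeR test (-3.96, Benjamini-Hochberg adjusted p = 0.0133). Adjusted over the list alone, 9 of 23 mural genes were lower, Pdgfrb among them at -1.90 (SE 0.32), and the list had a median of -1.20. The cell cycle list had a median of -0.03 and 0 members past either adjustment. Camera called lower, besides the mural genes, the lists for aerocytes (median -0.53), fibroblasts (-1.31), antigen presentation (-0.38), alveolar epithelium (-0.66), interferon response (-0.25), airway epithelium (-0.95), Wnt (-0.28) and Notch targets (-0.23). It called higher the tip and sprouting (0.43), venous (0.27), ribosomal protein (0.30) and arterial (0.19) lists. Each of these 13 lists had an adjusted p of 0.517 or more with an estimated correlation. By edgeR 2 genes were higher and 2 lower, while 1241 (6.37%) had an unadjusted p below 0.05. A regrouping of the same 6 libraries gave up to 2953 such genes. DESeq2 called 48 higher and 113 lower, and the groups did not overlap in 9.72% of genes, where chance gives 10%. The higher count was 10 without DNMAML replicate 2, 4 without Notch1f/f replicate 1, 1 without DNMAML replicate 3 and 0 without DNMAML replicate 1. The lower count was 21 without DNMAML replicate 2 and 8 without Notch1f/f replicate 3.

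Both genotypes were set beside each other against WT. Aspm was the only gene past the threshold in both comparisons. Simulated unchanged groups that shared a simulated WT group gave a mean of 0.025 genes, and independent lists 0.00513. All 9 libraries were simulated, so a peculiarity of the real WT libraries is not part of the simulated values. Of 745 genes with an unadjusted p below 0.05 in both, 744 moved the same way; the simulation gave 182 such genes, 99.1% of them the same way, and independent lists 157. Across genes, which are not independent replicates, the fold changes had a correlation of 0.619, where the simulation gave 0.502, and a covariance of 0.459, where it gave 0.25. The correlation was 0.449 without DNMAML replicate 2, 0.452 without Notch1f/f replicate 1 and up to 0.743 without WT replicate 2. The covariance was 0.368 without DNMAML replicate 2, 0.823 without WT replicate 2 and 0.295 with only the 6 libraries compared. The simulation was not repeated for these settings. With 3 WT libraries the controls could not be split, so part of the excess may come from the shared controls. The simulated genes were drawn independently of each other, while real genes deviated together between libraries. The simulation therefore cannot say how far such values vary by chance. A test of any difference among the 3 genotypes called 60 genes. That number was 5 without WT replicate 1 or 2, 11 without WT replicate 3, 17 without Notch1f/f replicate 2, 18 without DNMAML replicate 1, 37 without DNMAML replicate 3, 176 without DNMAML replicate 2 and 267 without Notch1f/f replicate 1. Aspm was the only shared call, and the shared count was 88 without Notch1f/f replicate 1, 7 without Notch1f/f replicate 3, 3 without DNMAML replicate 3, 2 without Notch1f/f replicate 2 and 0 without any other library.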

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

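The terms for sex, leukocyte markers and low Fos, the block in the 6 paired libraries, the halved counts and the legacy fit were chosen after the data had been seen; tests under all other settings were planned. Over settings, the named genes past the threshold kept direction and call in 900 values and fell short in 250, and the called lists kept both in 721, fell short in 151 and turned by camera's direction in 6. Except where a setting tests fewer genes or libraries, the cause was not tested. Depth limits genes near the floor of 0.108 to 0.193 CPM per library.

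For DNMAML against WT, the 1 higher and 0 lower genes became 361 and 99 without a filter, 177 and 38 with DESeq2, 65 and 13 with only the 6 libraries, 30 and 3 with a sex term, and 30 and 9 with a term for the low Fos libraries. The higher count was 0 with limma-voom, without robust estimation, with a leukocyte term and at an adjusted p below 0.01, where the log2 difference of Aspm was 3.58 to 3.84. Leaving out a library gave 0 to 84 higher and 0 to 10 lower.

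For Notch1f/f against WT, the 100 higher and 63 lower genes became 664 and 751 without a filter, 534 and 466 with DESeq2, 36 and 33 with limma-voom, 38 and 25 with a leukocyte term, and 11 and 6 at an adjusted p below 0.01; the sex term gave 156 higher. Leaving out a library gave 8 to 369 higher and 5 to 161 lower. The low Fos term gave 279 and 278. Of the 163 genes, 154 were called with the sex term, 60 with the leukocyte term, 159 with the low Fos term, 12, 17 and 44 without WT replicate 1, 2 or 3, 34 without Notch1f/f replicate 2 and 115 to 160 without another library, with no change of sign.

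Between Notch1f/f and DNMAML, the 2 higher and 2 lower genes became 176 and 520 without a filter, 48 and 113 with DESeq2, 0 and 1 with only the 6 libraries, and 6 and 4 with the low Fos term. The higher count was 1 without mitochondrial, ribosomal RNA and haemoglobin genes, with a sex term and at an adjusted p below 0.01. Leaving out a library gave 0 to 10 higher and 2 to 21 lower. For any difference among the genotypes, 60 genes became 1442 without a filter, 22 at 1 CPM, 784 with DESeq2, 10 with limma-voom, 33 without robust estimation, 115 with a sex term, 210 with the low Fos term, 8 with a leukocyte term, 28 with halved counts and 4 at an adjusted p below 0.01, and 5 to 267 without a library. The 1 gene shared by both comparisons with WT became 334 without a filter, 181 with DESeq2, 23 with the 6 libraries, 33 with a sex term, 34 with the low Fos term and 0 with limma-voom, without robust estimation, with a leukocyte term or at 0.01, and 0 to 88 without a library.

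From the data, the replicate number was taken to pair WT with DNMAML libraries and not the Notch1f/f ones. Of 9 same-numbered pairs 5 had correlated deviations over 0.1, and 5 of 9 libraries correlated best with their own number. WT and DNMAML replicate 2, the most correlated pair (0.344), are both low Fos libraries. They correlated about as much with the low Fos library Notch1f/f replicate 1 (0.352 and 0.306). Pairing and this shared structure cannot be told apart for that pair. Replicates 1 and 3 of WT and DNMAML gave 0.238 and 0.179, while the differently numbered DNMAML replicate 1 and Notch1f/f replicate 3 gave 0.219. The pairing of these libraries is therefore an assumption too. With the number as a block, DNMAML against WT gave 212 higher and 98 lower in the 6 paired libraries and 2 and 2 in all 9. Against the fit to all 9 libraries without a block, the block in the 6 libraries changed no call of a list by camera or by fry's directional test besides those given with that comparison. Fry's mixed test called 7 lists there (lowest adjusted p = 0.0226), 7 without the block (0.000834) and, with the block in all 9, the arterial and venous lists (0.0304). In all 9 libraries the block added the BMP and glycolysis lists as lower and the platelet and sex-linked lists as higher. There Notch1f/f against WT 149 lower, any difference 101 and the shared count 4; 46.6% of the Notch1f/f calls against WT were then higher.

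Notch1 in Notch1f/f against WT passed, by each tool's adjusted p, without a filter (-3.17, 2.33e-66), at 1 CPM (-3.16, 0.0498), with DESeq2 (-3.17, 3.17e-06), with limma-voom (-3.56, 0.0157), without robust estimation (-3.17, 0.0214) and with halved counts (-3.16, 0.0496), and was -4.05 to -2.74 without a library. It also passed without Notch1f/f replicate 2 (0.0381) or 3 (0.0093). Against DNMAML it passed without a filter (-3.08, 1.51e-62), with DESeq2 (-3.07, 7.13e-05) and with limma-voom (-3.46, 0.0297). Its log2 difference was -3.96 to -2.65 without a library, passing without Notch1f/f replicate 3 (0.0133). With the filter the log2 changes were the same and Notch1 did not pass. The values 2.33e-66 and 1.51e-62 are therefore not taken as measures of the spread between libraries. In DNMAML against WT, Notch1 reversed to 0.16 with the leukocyte term and was -0.18 to -0.01 without a library.

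In all 9 libraries, camera's estimated correlation and fry's directional test called 0 of the 39 fixed lists in each comparison, where the preset correlation called 8 higher and 7 lower, 3 and 5, and 4 and 9. Fry's mixed test, of change in either direction, called 0 for DNMAML and 20 for Notch1f/f against WT and 1 between them (lowest adjusted p = 0.208, 0.002 and 0.0049). In the 6 libraries without the block, the cell cycle list in DNMAML passed with an estimated correlation (0.0465) and with fry (0.00447), and with the block it did not (0.383 and 0.108). Lower lists in DNMAML were 4 at 1 CPM, with a sex term and with halved counts, 1 with a leukocyte term and 11 with the low Fos term. In Notch1f/f against WT, higher lists were 6 without a filter, with the block and with a leukocyte term and 5 with a sex or low Fos term; lower lists were 9, 10 and 8 without a filter, with the block and with a leukocyte term. Without a library, lists ran from 3 to 13 higher and 3 to 12 lower in DNMAML, 2 to 7 and 5 to 12 in Notch1f/f, and 2 to 11 and 5 to 12 between them. Camera's direction turned for leukocyte markers in DNMAML (median -0.0948 with the leukocyte term), alveolar genes in DNMAML (0.28 with the leukocyte term, 0.27 without WT replicate 3, 0.01 without DNMAML replicate 2, lowest -0.506), antigen presentation in DNMAML (-0.0344 without DNMAML replicate 1, highest 0.357) and ribosomal proteins between Notch1f/f and DNMAML (0.0457 without Notch1f/f replicate 3, a median still above 0; highest 0.597). With a sex term the alveolar median in DNMAML was 0.368 while camera still called the list lower (adjusted p = 0.0269), so median and test differed in sign.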

Other observations

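The tests of explanations and both added gene lists were chosen, and the criteria for the regrouped libraries written, only after the results had been seen. Of 30 tested p53 targets 24 were higher in DNMAML than in WT, with a median log2 difference of 0.44; 0 passed over all genes and 11 were higher when adjusted over the list alone. In Notch1f/f the median was 0.47, 3 rose over all genes (Eda2r, Psrc1 and Ckap2), and 15 were higher and 2 lower when adjusted over the list alone. Eda2r, a receptor gene induced by p53, had 2.29, 3.97 and 3.98 CPM in WT, 31.3, 19.5 and 13.1 CPM in DNMAML, and 32.4, 32.1 and 15.9 CPM in Notch1f/f. Psrc1, Ckap2 and Gtse1 of this list also act in mitosis. The list was chosen after values of its genes had been seen, so its tests are no independent evidence. Adjusted over 41 lists, the fixed ones and those added, camera called it in both at its preset correlation (adjusted p = 3.24e-10 and 4.19e-07). With an estimated correlation, it gave the list an adjusted p = 0.48 in DNMAML and 0.666 in Notch1f/f, and fry's directional test gave 0.683 and 0.205.

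Of the 19 circadian genes tested, 0 passed over all genes in either genotype. Nr1d1, a repressor of the clock, had 439, 331 and 227 CPM in WT, 137, 60.1 and 138 CPM in DNMAML, and 113, 156 and 143 CPM in Notch1f/f. In DNMAML 12 were lower and 7 higher, with a median of -0.62, and 4 were lower when adjusted over the list alone. In Notch1f/f 13 were lower and 6 higher, with a median of -0.24, and 2 were lower when adjusted over the list alone. Camera called the list lower in DNMAML at its preset correlation (adjusted p = 0.00135, over the same 41 lists), and gave an adjusted p = 0.486 with an estimated correlation, where fry's directional test gave 0.755. For Notch1f/f these were 0.173, 0.823 and 0.585. The time of day of collection is not given in the sources used here. In Notch1f/f, Gt(ROSA)26Sor rose to 11.4, 8.72 and 6.60 CPM from 0.624, 0.769 and 1.63 CPM in WT, and had 1.76, 3.80 and 3.62 CPM in DNMAML. Ssu2, also on chromosome 6, rose to 7.47, 13.4 and 6.43 CPM in Notch1f/f from 0.416, 0.385 and 1.43 CPM in WT, and had 0.561, 2.30 and 2.19 CPM in DNMAML. Neither gene passed in DNMAML against WT or between Notch1f/f and DNMAML, and both were chosen after their values were seen.

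Cell cycle genes were higher in DNMAML and in Notch1f/f than in WT. Leukocytes carried into the sort are argued against as the whole source: in the 3 DNMAML and Notch1f/f libraries whose Ptprc, Laptm5 and Coro1a lay mostly within the WT range, the list's mean log2 CPM was still at least 2.09 above the highest WT library. A different mix of sexes is argued against too: among libraries of the same sex, the lowest DNMAML or Notch1f/f library was still at least 0.83 above the highest WT library. This smallest gap was among males, where the only WT library, replicate 2, had 1.44 and Notch1f/f replicate 1 had 2.27. WT and Notch1f/f held 1 male library each. A peculiarity shared by the 3 WT libraries stays open, since WT is the only reference. A genotype effect on division of endothelial cells stays open and was not tested.

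Mural genes were lower in Notch1f/f than in WT. A smaller share of mural cells in the sort cannot be told apart from a change of expression. The 16 members at 10 CPM or more deviated together between libraries of a genotype, with a mean correlation of 0.569. For 1000 random lists matched on expression, the 95th percentile was 0.105. But cell cycle, immediate early and ribosomal protein genes, which mark no cell type, gave 0.683, 0.763 and 0.929. The mural gene Rgs5 had 13.4, 13.3 and 16.2 CPM in WT and 20.9, 21.3 and 23.1 CPM in Notch1f/f. Less RNA from other lung cells carried over cannot be told apart either: the fibroblast, alveolar and airway epithelium lists had medians of -0.86 or lower, but were not called with an estimated correlation. The airway list was not called at the preset correlation either (camera, adjusted p = 0.0563). A change of expression in mural cells or of their number in the lung stays open and was not tested.

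In Notch1f/f, mt-Nd3 was higher and Gm28438 lower. More mitochondrial RNA is argued against, since the other 12 mitochondrial protein genes had a median log2 difference of 0.38 and none exceeded 0.77. Reads assigned to the other of 2 near-identical copies are a candidate explanation: the transcripts match over 345 bases with 1 mismatch, mt-Nd3 held 58.8% to 60.7% of their summed CPM in Notch1f/f and at most 1.21% elsewhere, and the log2 ratio of the sum to WT was -0.70. Whether the mice carry different mitochondrial sequences was not tested and stays open.

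With 3 libraries against 3 there are 10 splits, too few for a share below 0.05. For DNMAML against WT, 1 of 10 splits, the real one, gave as many as its 1 gene, and the highest other gave 0. Splits that part all 3 WT and DNMAML pairs number 4, and had 1164 genes (the real one), 320, 153 and 93 at an unadjusted p below 0.05. The 6 that keep pairs together had 388 to 933. With the block in these 6 libraries the first 4 gave 310, 0, 4 and 0 genes past the threshold. For Notch1f/f against WT, 1 of 10 gave as many as the real 163 genes, and the highest other gave 0. For Notch1f/f against DNMAML, 1 of 10 gave as many as the real 4 genes, and the highest other gave 2. At an unadjusted p below 0.05, the real split of Notch1f/f and WT had 2620 genes and the highest other 2157. The real split of Notch1f/f and DNMAML had 1241, while other splits had 2953 and 1410. That number therefore does not set the genotypes apart. Camera at its preset correlation called many lists under regrouped libraries: 6, 7 and 9 of the 10 splits gave as many as the real 15, 8 and 13 lists, and the highest others gave 24, 19 and 19. For any difference among the 3 genotypes, 4 of 100 drawn splits of the 9 libraries gave as many as the real 60 genes, a share just below 0.05 in a draw from 280. The splits exchange paired libraries and those that stand apart freely, so this is not taken to exclude chance. The others gave 81, 93 and 184 genes, and the last, several times the real count, points to a structure among the libraries other than genotype.

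WT replicate 2, DNMAML replicate 2 and Notch1f/f replicate 1 stood apart together. The deviations of these 3 libraries from their group means correlated at 0.306 to 0.352, and on the second principal component (21.9% of the variance) they had scores of 76.9, 43.3 and 59.1, with 8.3 or lower in the others. Fos, an immediate early gene, had 319, 345 and 495 CPM in them and 1230 to 2010 CPM in the others. The 4 drawn splits that put them in a single group gave 93, 81, 54 and 45 genes, and the others, apart from the real split and that of 184 genes, gave 7 or fewer. The split with 184 genes grouped DNMAML replicate 2 with Notch1f/f replicates 1 and 2, which had scores of 49, 62.2 and 108 on the first component (26.7%), with -0.653 or lower in the others. Each genotype held 1 of the 3 low Fos libraries. With a term for them 210 genes differed among the genotypes, 279 were higher and 278 lower in Notch1f/f than in WT, and 30 and 9 in DNMAML.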
